A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

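RNA was measured in biofilms of 7 Saccharomyces cerevisiae strains of the Sigma1278B background, 3 libraries each. Per the labels' protocols, strains were grown for 16 h in rich glucose liquid medium at 30 °C, brought to an optical density of 20, spotted in 10 µl on rich galactose agar and harvested after 24 h. RNA was extracted with hot acid phenol, polyadenylated RNA was selected, and libraries were made with the TruSeq RNA Sample Prep Kit, per the labels. Groups and replicate numbers were taken from the labels, which give each strain's mutation and its filamentous phenotype. Per the submitters' processing notes, which name tools and not their roles or settings, the reads went through bcl2fastq, TopHat2 2.0.19 and HTSeq 0.6.1 with genome build R64. The filters, the annotation version and the strand setting are not given in the sources used here. The deposited values were whole-number counts of reads per gene, not normalized, in 1 table per library.

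Each deposited count table held 7126 features, 6048 of which matched a locus tag of the RefSeq R64 gene table, from which symbols and coordinates were taken. The totals of alignment records that HTSeq gave to no gene, as without a feature, ambiguous or not unique, were left out of library sizes and tests, and they made up 40.1% to 47.8% of all alignment records of a library. A fragment aligned to several places adds several such records, so these are not shares of reads. The deposited counts on features came to 2388813 to 3987529 per library, which is a modest depth, so that genes with low counts had little power. Replicates were compared before averaging, and all pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.93 to 56.9. Reads of Sigma1278B strains were aligned to a reference from another strain background, so genes that differ between them can be undercounted alike in all groups. Genes of near-identical families, overlapping genes and antisense genes are uncertain, since the counting of such reads is not given in the sources used here.

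Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group (5786 genes), TMM factors ranged from 0.893 to 1.16, and 1 quasi-likelihood model with a mean per group was fitted to all 21 libraries, so that they shared 1 estimate of the spread per gene. Each mutant was tested against the wild type and dig1 against ste12, with two-sided tests, Benjamini-Hochberg adjustment over the tested genes of a comparison and a threshold of 0.05. Before the data were examined, 38 gene lists were fixed: filamentation MAPK pathway components, filamentation MAPK target genes, pheromone response genes, a-specific genes, alpha-specific genes, meiosis and sporulation genes, flocculins and adhesins, cell wall proteins, hypoxic cell wall genes, seripauperins, cyclins, core histones, galactose pathway, hexose transporters, glycolysis and ethanol formation, gluconeogenesis, glyoxylate and fatty acid oxidation, retrograde pathway targets, tricarboxylic acid cycle, respiratory chain and ATP synthase, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, ribosome biogenesis, Msn2/Msn4 stress genes, trehalose and glycogen, heat shock and chaperones, Ras and protein kinase A pathway, SAGA subunits, Rim101 pathway components, Rim101 regulated genes, nitrogen catabolite repression genes, general amino acid control, sulfur and methionine metabolism, phosphate regulon, iron regulon, ergosterol synthesis, strain construction genes, the mitochondrially encoded genes and 1 list that was tested and counted with the others and is not reported here. Lists of at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, the adjustment being over 36 lists. The gene that names a mutant was left out of its lists. None of the mitochondrially encoded genes passed the filter on low counts, so that list gave no result. Ratios of the targeted genes have exact conditional 95% intervals, and a gene without counts was set at a floor of 3 counts over the group. For correlations and overlaps between comparisons that share the wild type, unchanged groups were simulated against the same libraries.

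The named genes followed a rule fixed before the data were examined. It took the gene that names each mutant, and the 8 largest rises and falls among named genes that passed the test, did not overlap between the groups in log2 CPM, and had a mean count of at least 50 in the higher group. It also took up to 4 members, by smallest p, of each list that passed and of the lists bearing on filamentation, FLO11 throughout, and for the shared genes up to 10 per direction. Of the genes so picked, the text names mainly those whose call held in every alternative. The alternatives fixed at the same time were the Wald test of DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, the replicate number as a block, only the libraries of both groups in the fit, each library left out in turn, and camera with an estimated correlation. A comparison of each mutant with the mean of the 5 other mutants was added after the data were seen. Simulated data were made for all 21 libraries from the rates of their groups, with the ste12 rates replaced by those of the wild type. The scheme was tested on the comparison of ste12 with the wild type, over 5768 genes with 200 changed. It recovered 46% of the genes changed 1.5-fold, 86% at 2-fold, 100% at 4-fold and 84% at 0.5-fold, and 9 of 167 calls (5.39%) were of unchanged genes. A list changed 1.5-fold passed camera (adjusted p = 6.46e-40), with 0 of the other lists passing. The simulated genes were drawn without correlation between them, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.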

Results

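Biofilms of the Sigma1278B background of the budding yeast Saccharomyces cerevisiae were grown for 24 h on agar with galactose, and their polyadenylated RNA was sequenced. Sigma1278B is a laboratory background that can form filaments, invade agar and build mats, which most common laboratory strains have lost. The series held 21 libraries in 7 groups of 3: the wild type, a dig1 mutant that the labels call hyperfilamentous, and ste12, spt8, rim101-531, ras2 and rtg3 mutants that they call hypofilamentous. STE12 encodes the transcription factor at the end of the mitogen-activated protein kinase (MAPK) pathways for filamentation and mating, and DIG1 encodes a repressor of Ste12. SPT8 encodes a subunit of the SAGA coactivator, RIM101 a repressor that acts in the response to alkaline pH, RAS2 a GTPase upstream of protein kinase A, and RTG3 a transcription factor of the retrograde signal from mitochondria to the nucleus. Counts on features ranged from 2388813 (ste12 replicate 1) to 3987529 (ras2 replicate 3) per library. The group means ran from 2464960 ± 124915 in ste12 to 3745910 ± 361802 in ras2. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over n = 3 libraries, and log2 fold changes as the estimate ± its standard error. Gene lists were tested with camera, and beside a list that passed, an adjusted p with an estimated correlation is given wherever that ended its call. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

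The gene that names each mutant was examined in all 7 groups before any other gene. SPT8 had no count in the 3 spt8 libraries and 195 counts over the 3 wild-type libraries, RAS2 had none in ras2 against 954, and RTG3 had none in rtg3 against 319. At a floor of 3 counts over the mutant group, the wild type was 63.5-fold higher for SPT8, 402-fold higher for RAS2 and 135-fold higher for RTG3, with exact lower 95% limits of 51.1, 327 and 109.5 on the ratios. DIG1 had 1 count over the dig1 libraries and 549 over the wild-type libraries, a ratio of wild type to dig1 of 535 (95% interval 95.7 to 21182). STE12 counts remained in ste12, at 28.0 ± 3.60 CPM against 59.0 ± 8.79 CPM in the wild type, so the counts check that label only in part (log2 fold change -1.08 ± 0.16, adjusted p = 0.000108). RIM101 stood at 164 ± 18.5 CPM in rim101-531 and 182 ± 10.8 CPM in the wild type and did not pass the test (log2 fold change -0.16 ± 0.11, adjusted p = 0.527), so counts per gene do not check the rim101-531 label. In the groups other than its own mutant, STE12 lay between 44.5 ± 4.19 (rtg3) and 64.5 ± 8.90 CPM (dig1), DIG1 between 49.5 ± 5.08 (spt8) and 62.5 ± 0.543 CPM (ras2), and SPT8 between 21.3 ± 1.77 (ste12) and 27.5 ± 1.33 CPM (ras2). RIM101 lay between 141 ± 7.44 (spt8) and 219 ± 1.95 CPM (rtg3), RAS2 between 90.5 ± 26.5 (spt8) and 142 ± 36.7 CPM (rim101-531), and RTG3 between 35.1 ± 4.78 (wild type) and 44.0 ± 7.30 CPM (spt8). The intervals and floors cover counting error only.

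FLO11 (YIR019C, chromosome IX, 389572 to 393675 in R64) encodes the cell surface flocculin needed for filaments, mats and adhesion to agar, and it separated the mutants widely. Its transcript stood at 16473 ± 1892 CPM in the wild type, 1.59% of all counts. In dig1 it rose 2.08-fold to 34272 ± 394 CPM (log2 fold change 1.06 ± 0.14, adjusted p = 1.97e-05). It fell in 4 of the 5 hypofilamentous mutants: 23.7-fold in rtg3 (696 ± 15.8 CPM, adjusted p = 6.06e-14), 8.54-fold in spt8 (1928 ± 82.9 CPM, adjusted p = 2.86e-11), to 3295 ± 685 CPM in ste12 (log2 fold change -2.32 ± 0.14, adjusted p = 2.12e-09) and 2.41-fold in ras2 (6829 ± 534 CPM, adjusted p = 2.29e-06). In rim101-531 it stood at 12647 ± 386 CPM and did not pass the test (log2 fold change -0.38 ± 0.14, adjusted p = 0.145). PGU1 (YJR153W, chromosome X, 722815 to 723900), which encodes a secreted pectin-cleaving enzyme used as a reporter of the filamentation pathway, fell in all 5 hypofilamentous mutants and rose in dig1. It went from 101 ± 7.41 CPM in the wild type to 7.27 ± 1.81 in ste12, 14.3 ± 1.12 in rtg3, 17.6 ± 3.34 in ras2, 27.5 ± 5.89 in spt8, 51.2 ± 9.68 in rim101-531 and 1302 ± 53.8 in dig1. The largest of the 6 adjusted p-values for PGU1 was 0.00109, in rim101-531.

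**Figure D1:**
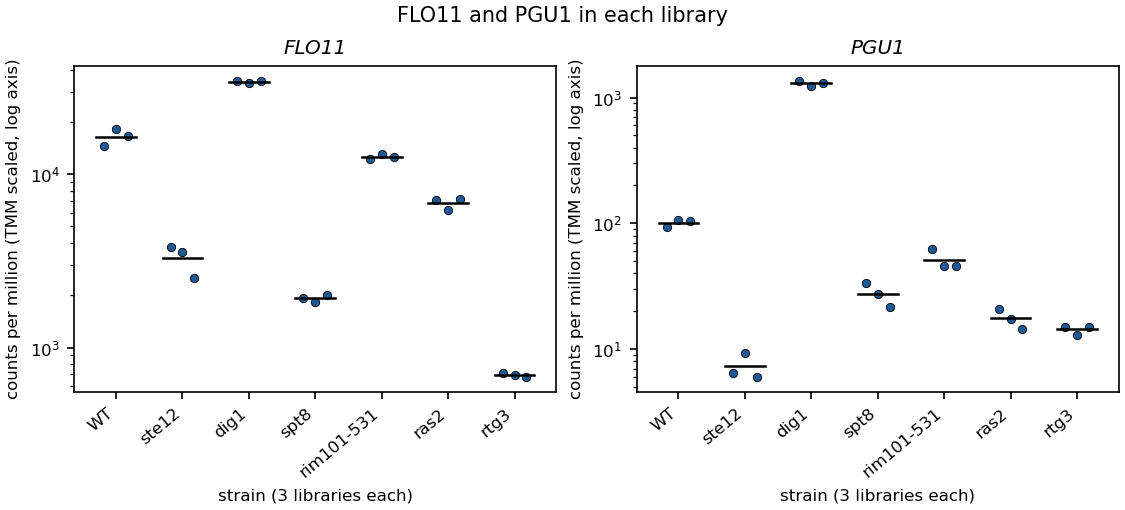
FLO11 and PGU1 in CPM (log axis) in each of the 21 libraries, with each point 1 library and each bar the mean of its group. FLO11 runs from 696 ± 15.8 CPM in rtg3 to 34272 ± 394 in dig1, and PGU1 from 7.27 ± 1.81 in ste12 to 1302 ± 53.8 in dig1.

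The ste12 mutant asked which biofilm transcripts need the filamentation and mating transcription factor. Ste12 acts with Tec1 on filamentation genes and with Mcm1 on genes of the a mating type. Known Ste12 targets were among the largest losses in ste12. NFG1, a negative regulator of filamentous growth, went from 248 ± 15.3 to 1.35 ± 0.473 CPM (log2 fold change -7.48 ± 0.30, adjusted p = 4.91e-12), and PGU1 dropped 13.8-fold. All 11 tested filamentation MAPK target genes fell (11 adjusted over the list alone; camera adjusted p = 2.95e-55), among them MSB2, the mucin sensor of the pathway (-1.81 ± 0.12), TEC1, the partner of Ste12 (-1.34 ± 0.14), and KSS1, its kinase (-0.95 ± 0.13). Of the 22 tested pheromone response genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.41e-13). PRM5, a pheromone-regulated membrane protein, had a log2 fold change of -3.04 ± 0.20. The gene that rose was FUS1 (0.38 ± 0.11, adjusted p = 0.0404). The pheromone list holds all the a-specific genes, so the results of these lists overlap in every comparison. The a-specific genes, expressed in MATa cells, lost 4 of 5 tested members (4 adjusted over the list alone; camera adjusted p = 1.50e-15): BAR1, a protease that degrades alpha factor (log2 fold change -2.99 ± 0.23), STE6, the exporter of a factor (-1.25 ± 0.08), AGA2, a mating adhesin (-1.65 ± 0.35), and STE2, the receptor for alpha factor. The other large named falls were of NDJ1, a telomere protein of meiosis (-4.64 ± 0.25), AFB1, a barrier to a factor (-3.04 ± 0.20), FRE2, a ferric reductase (-2.80 ± 0.47), and SRD1 (-2.59 ± 0.20). FRE2 varied widely among the wild-type libraries, at 116 ± 95.3 CPM. Of the filamentation MAPK pathway components 5 of 15 fell (7 adjusted over the list alone; camera adjusted p = 7.99e-08).

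Transcripts of cell surface genes moved in both directions in ste12. Cell wall proteins fell in 12 and rose in 3 of 32 cases (13 and 3 adjusted over the list alone; camera adjusted p = 4.49e-08). CWP1 had a log2 fold change of -2.17, CWP2 of -1.56, SVS1 of -1.66 and SCW10 of -0.89. Flocculins and adhesins fell in 3 of 8 cases and rose in none (5 adjusted over the list alone; camera adjusted p = 1.33e-06), FLO11 and the mating adhesin AGA1 (-1.23) among them. Hypoxic cell wall genes rose in 8 of 12 cases (11 adjusted over the list alone; camera adjusted p = 3.70e-18), among them the mannoproteins TIR4 (1.82), TIR2 (1.40) and DAN1 (1.24) and the hypoxic translation factor ANB1 (2.07). The seripauperins, near-identical cell wall genes whose reads can be shared, rose in 4 of 5 cases (5 adjusted over the list alone; camera adjusted p = 4.33e-06).

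Phosphate genes also rose in ste12. The largest rise was of PHO89, a sodium and phosphate symporter, from 7.84 ± 0.445 to 243 ± 98.5 CPM (log2 fold change 4.94 ± 0.40, adjusted p = 4.66e-08), followed by CSS1 (3.57 ± 0.26), SPL2, a regulator of phosphate uptake (2.52 ± 0.42), URA3, an enzyme of uracil synthesis (2.36 ± 0.16), and HES1, a sterol-binding protein (2.30 ± 0.23). PAU2, a seripauperin (2.29 ± 0.41), ANB1 and CMK2, a calmodulin-dependent kinase (2.00 ± 0.13), completed the largest rises. For URA3 a selection marker in the ste12 strain cannot be told apart from regulation. The phosphate regulon rose in 10 and fell in 0 of 16 cases (13 and 0 adjusted over the list alone; camera adjusted p = 1.49e-18). Of the transporters, PHO84 had a log2 fold change of 1.65 and GIT1 of 1.68. Ergosterol synthesis rose in 12 of 24 cases (14 adjusted over the list alone), ERG6, ERG11 and ERG25 by 0.78, 0.82 and 0.82 on the log2 scale (camera adjusted p = 2.11e-07, adjusted p = 0.128 with an estimated correlation). Glycolysis rose in 7 of 21 cases (9 adjusted over the list alone), TDH1 by 1.57 and ENO2 by 1.04 (camera adjusted p = 9.38e-06, adjusted p = 0.357 with an estimated correlation). Heat shock genes rose in 6 of 27 (7 adjusted over the list alone), BTN2 by 1.51 (camera adjusted p = 0.000193, adjusted p = 0.255 with an estimated correlation). Of the galactose pathway 1 of 10 members fell and 0 rose (1 and 0 adjusted over the list alone), and it did not move as a list (camera adjusted p = 0.586); GAL1, the galactokinase, stood at 3952 ± 1328 CPM in ste12 and 3255 ± 679.9 in the wild type. None of the 3 tested alpha-specific genes passed, over all genes or adjusted over the list alone, and they were too few for camera. In all, 577 of the 5786 tested genes changed, 276 of them higher and 301 lower, 70 and 64 of them by at least 2-fold. Of 36 lists 20 passed camera, 11 of them with an estimated correlation. The count was 357 without wild-type replicate 3, 370 without ste12 replicate 3, and 1581 against the mean of the 5 other mutants, a reference chosen after the data were seen.

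Dig1 holds Ste12 inactive until a MAPK releases it, so its loss frees Ste12 in the absence of a signal. The dig1 biofilms had higher filamentation, mating and adhesion transcripts than the wild type. PGU1 rose 12.8-fold, and FLO10, a second flocculin, rose 18.7-fold from 53.8 ± 13.1 to 1005 ± 10.9 CPM (log2 fold change 4.22 ± 0.28, adjusted p = 5.48e-09). Of the 12 filamentation MAPK target genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.60e-18), among them SVS1 (log2 fold change 1.59 ± 0.12), NFG1 (1.45 ± 0.17) and KSS1 (0.96 ± 0.11). Pheromone response genes rose in 15 and fell in 0 of 22 cases (17 and 0 adjusted over the list alone; camera adjusted p = 1.23e-17). PRM5 had a log2 fold change of 2.59 ± 0.14. The a-specific genes rose in 4 of 5 cases (4 adjusted over the list alone; camera adjusted p = 3.06e-12): AGA2 (2.37), BAR1 (2.27), STE2 (1.05) and STE6 (0.74). Flocculins and adhesins rose in 4 of 8 cases (4 adjusted over the list alone; camera adjusted p = 1.65e-07), the others being FLO11, AGA1 (1.78) and FIG2 (0.63). Pathway components rose in 3 and fell in 1 of 15 cases (4 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0735); without wild-type replicate 2 it did (adjusted p = 0.0397, the lowest over the settings tried, the highest being 0.110). Seripauperins rose in 4 of 5 cases (5 adjusted over the list alone; camera adjusted p = 3.74e-16), PAU17 by 3.00 and PAU5 by 2.42 on the log2 scale, and hypoxic cell wall genes rose in 7 and fell in 1 of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 8.78e-05, adjusted p = 0.189 with an estimated correlation).

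Other large rises in dig1 were of single genes. PHO89 rose from 7.84 ± 0.445 to 252 ± 53.6 CPM (adjusted p = 5.77e-08), ZPS1, a zinc-regulated surface protein, by 4.75 ± 0.46 on the log2 scale, ZRT1, the high-affinity zinc transporter, by 3.16 ± 0.45, and GIT1, a permease for glycerophosphoinositol, by 2.78 ± 0.19. The phosphate regulon rose in 8 and fell in 1 of 16 cases (9 and 1 adjusted over the list alone; camera adjusted p = 4.36e-08, adjusted p = 0.0553 with an estimated correlation), including PHO84 (1.11) and the acid phosphatase PHO11 (2.34). Ergosterol synthesis rose in 8 of 24 cases (16 adjusted over the list alone; camera adjusted p = 4.21e-05, adjusted p = 0.272 with an estimated correlation), ERG1 by 0.91 and ERG2 by 0.53. The largest falls held MRH1, a membrane protein (-1.96 ± 0.15), URA1, an enzyme of uracil synthesis (-1.83 ± 0.24), YGP1, a secreted glycoprotein of stress and starvation (-1.65 ± 0.22), RIB4, an enzyme of riboflavin synthesis (-1.64 ± 0.14), YRO2 (-1.59 ± 0.27) and DSE4 (-1.47 ± 0.19). Respiratory chain and ATP synthase genes fell in 17 of 34 cases and rose in 0 (26 and 1 adjusted over the list alone; camera adjusted p = 1.29e-07, adjusted p = 0.355 with an estimated correlation). Mitochondrial ribosomal proteins fell in 13 of 56 (15 adjusted over the list alone; camera adjusted p = 1.71e-07, adjusted p = 0.455 with an estimated correlation). Stress genes under Msn2 and Msn4 fell in 11 of 30 cases (13 adjusted over the list alone; camera adjusted p = 9.62e-07, adjusted p = 0.342 with an estimated correlation), SPI1 at -1.07 ± 0.11 on the log2 scale and NQM1 at -1.31 ± 0.18, and heat shock genes in 8 of 27 (8 adjusted over the list alone; camera adjusted p = 0.000590, adjusted p = 0.307 with an estimated correlation). Rim101-regulated genes rose in 4 and fell in 1 of 8 cases (5 and 1 adjusted over the list alone; camera adjusted p = 0.00786, adjusted p = 0.0553 with an estimated correlation). ENA1, a sodium pump, had a log2 fold change of 1.16. In all, 909 of the 5786 tested genes changed, 464 of them higher and 445 lower, 140 and 55 of them by at least 2-fold. Of 36 lists 22 passed camera, 5 of them with an estimated correlation. With the 6 libraries of both groups alone in the fit the count was 385. Alignments to more than 1 place made up 27.9% ± 0.654 of the alignment records in dig1 and 21.2% ± 0.417 in the wild type, so genes with near-identical copies, the FLO and PAU families among them, are the least certain here.

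Ste12 and its repressor Dig1 act at the same promoters in opposite senses, and dig1 was therefore also set directly against ste12. Filamentation, mating and adhesion genes were higher in dig1, and most heat shock genes were higher in ste12. NFG1 stood at 678 ± 15.9 CPM in dig1 and 1.35 ± 0.473 in ste12 (log2 fold change 8.93 ± 0.30, adjusted p = 3.88e-14), PGU1 was 177-fold higher in dig1 (adjusted p = 3.58e-15), and FLO11 10.4-fold higher (adjusted p = 2.17e-12). All 11 tested filamentation target genes were higher in dig1 (11 adjusted over the list alone; camera adjusted p = 1.68e-66), as were 9 of the 14 pathway components (10 adjusted over the list alone; camera adjusted p = 1.82e-07). MSB2 had a log2 fold change of 1.86, KSS1 of 1.90 and TEC1 of 1.87. Of the 22 pheromone response genes 16 were higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 4.96e-30), and of the 5 a-specific genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 2.44e-25). PRM5 differed by 5.62 ± 0.19, BAR1 by 5.26 ± 0.23, FLO10 by 5.35 ± 0.31, NDJ1 by 5.43 ± 0.23, AFB1 by 4.11 ± 0.19 and ZPS1 by 5.70 ± 0.49 on the log2 scale. Cell wall proteins were higher in 18 and lower in 3 of 32 cases (22 and 6 adjusted over the list alone; camera adjusted p = 1.11e-07). Flocculins and adhesins were higher in 5 of 8 (5 adjusted over the list alone; camera adjusted p = 6.38e-13). Rim101-regulated genes were higher in 4 of 8 cases (4 adjusted over the list alone; camera adjusted p = 0.000538). RIM8, an arrestin of the Rim101 pathway, had a log2 fold change of 2.12. DSE4, a glucanase (-3.04 ± 0.18), URA3 (-2.36 ± 0.16), EGO4 (-2.26 ± 0.27), CSS1 (-2.22 ± 0.24), HOR7 (-1.94 ± 0.19), ICS2 (-1.89 ± 0.12), the glycolytic TDH1 (-1.88 ± 0.28) and GPM2 (-1.78 ± 0.30) were the largest differences in favour of ste12. The difference of URA3 may be that of a selection marker, which cannot be told apart from regulation. Heat shock genes were lower in dig1 in 17 of 27 cases (18 adjusted over the list alone; camera adjusted p = 5.34e-08, adjusted p = 0.0695 with an estimated correlation). In all, 1255 genes differed, 672 higher in dig1 and 583 lower, and the count was 603 with only the 6 libraries of both mutants in the fit. NFG1 overlaps YLR041W, and since the strand setting of the counting is not given in the sources used here, reads of the pair cannot be told apart.

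**Figure D2:**
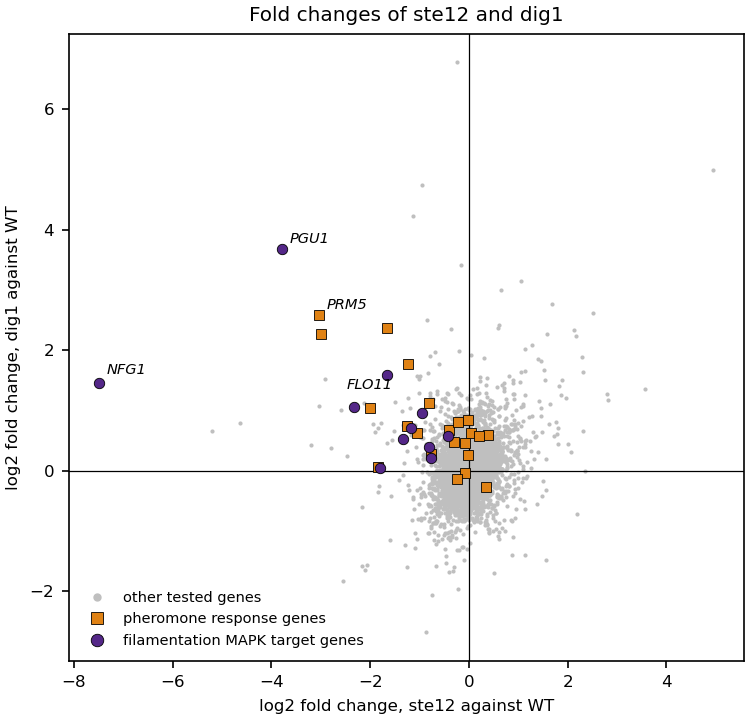
Log2 fold change of each tested gene in ste12 (horizontal) and dig1 (vertical) against the wild type, with pheromone response genes as orange squares, filamentation target genes as purple circles, all other genes in gray, and STE12 and DIG1 left out. PGU1 lies at -3.79 in ste12 and 3.68 in dig1, and FLO11 at -2.32 and 1.06; both axes share the wild-type libraries.

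Spt8 is the SAGA subunit that contacts the TATA-binding protein, and SAGA serves many stress-induced and highly regulated promoters. Its loss changed 1474 genes, close to the 1462 of ras2, and which of the mutants had the most depended on the settings. Most respiratory and glycolytic genes and Msn2/Msn4 stress genes fell, and part of the amino acid and sulfur genes rose, though none of these lists passed with an estimated correlation. Respiratory chain and ATP synthase genes fell in 31 of 34 cases (32 adjusted over the list alone, with 1 higher), with a median log2 fold change of -1.05 (camera adjusted p = 7.02e-30, adjusted p = 0.171 with an estimated correlation). COX13, a cytochrome oxidase subunit, had a log2 fold change of -1.34 ± 0.09 and QCR7, of the bc1 complex, of -1.51 ± 0.12. Mitochondrial ribosomal proteins fell in 43 of 56 cases (46 adjusted over the list alone; camera adjusted p = 8.92e-12, adjusted p = 0.401 with an estimated correlation), among them MRPL51 (-1.04) and MRPS5 (-0.81). The tricarboxylic acid cycle fell in 7 and rose in 2 of 17 cases (12 and 2 adjusted over the list alone; camera adjusted p = 0.00471, adjusted p = 0.632 with an estimated correlation). KGD2 had a log2 fold change of -1.34 and SDH4 of -1.21. Glycolytic genes fell in 14 and rose in 1 of 21 (15 and 1 adjusted over the list alone; camera adjusted p = 6.31e-07, adjusted p = 0.401 with an estimated correlation), the aldolase FBA1 from 8359.7 ± 1139 to 2416 ± 340.0 CPM (log2 fold change -1.79 ± 0.13, adjusted p = 1.03e-08), TDH3 at -1.62 ± 0.22 and ADH1 at -1.44 ± 0.20. Genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation fell in 10 and rose in 1 of 22 cases (11 and 2 adjusted over the list alone; camera adjusted p = 6.27e-05, adjusted p = 0.457 with an estimated correlation). YAT1, a carnitine acetyltransferase, had a log2 fold change of -2.52 and MDH2 of -2.39. Stress genes under Msn2 and Msn4 fell in 20 and rose in 1 of 30 cases (22 and 1 adjusted over the list alone; camera adjusted p = 3.64e-12, adjusted p = 0.267 with an estimated correlation), DDR2 at -2.48 ± 0.22 and NQM1 at -2.04 ± 0.19 on the log2 scale.

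FLO11 was among the largest falls in spt8, beside CRS5, a copper-binding metallothionein (-3.32 ± 0.18), the hydrophilins SIP18 (-3.01 ± 0.22) and GRE1 (-2.95 ± 0.20), YPC1, a ceramidase (-2.81 ± 0.23), COX26, a cytochrome oxidase subunit (-2.78 ± 0.29), and CWP1, a cell wall mannoprotein (-2.77 ± 0.20). Cell wall proteins fell in 13 and rose in 4 of 32 cases (15 and 4 adjusted over the list alone; camera adjusted p = 7.19e-05, adjusted p = 0.267 with an estimated correlation), EXG1 at -1.48 ± 0.13 and CWP2 at -1.24 ± 0.11. Of the filamentation target genes 5 of 12 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 8.84e-05, adjusted p = 0.171 with an estimated correlation), TEC1 at -0.81 ± 0.13 and MSB2 at -0.67 ± 0.11. The iron regulon fell in 14 of 23 cases (18 adjusted over the list alone; camera adjusted p = 5.47e-05, adjusted p = 0.457 with an estimated correlation). FRE2 had a log2 fold change of -3.03 ± 0.46, FIT1, a siderophore-binding mannoprotein, of -2.46 ± 0.45 and FTR1, an iron permease, of -1.65 ± 0.26, on wild-type levels that varied widely (FIT1 46.8 ± 32.1 CPM). PHO89 (3.89 ± 0.40), HUG1, an inhibitor of ribonucleotide reductase (3.83 ± 0.28), HES1 (2.29 ± 0.23), GIT1 (2.10 ± 0.19), CSS1 (2.08 ± 0.27), PBI1 (1.91 ± 0.23), BTN2, a chaperone of protein sorting (1.90 ± 0.19), and EFM6, a methyltransferase (1.89 ± 0.24), had the largest rises. Amino acid synthesis under general control rose in 12 and fell in 1 of 32 cases (13 and 2 adjusted over the list alone; camera adjusted p = 0.000161, adjusted p = 0.563 with an estimated correlation), LEU1 by 1.33 and LEU4 by 1.05 on the log2 scale. Sulfur and methionine genes rose in 12 of 25 (14 adjusted over the list alone; camera adjusted p = 3.93e-05, adjusted p = 0.401 with an estimated correlation), MET10 by 1.09. Hypoxic cell wall genes rose in 8 and fell in 1 of 12 cases (8 and 1 adjusted over the list alone; camera adjusted p = 6.27e-05, adjusted p = 0.267 with an estimated correlation). The phosphate regulon rose in 8 and fell in 1 of 16 (8 and 1 adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.267 with an estimated correlation). The other SAGA subunits rose in 1 and fell in 2 of 18 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.276). Meiosis and sporulation genes rose in 1 and fell in 2 of 19 (likewise 1 and 2 adjusted over the list alone; camera adjusted p = 0.951), hexose transporters likewise in 1 and 1 of 12 (1 and 1 adjusted over the list alone; camera adjusted p = 0.738). The genes used in strain construction rose in 3 and fell in 0 of 12 (3 and 0 adjusted over the list alone; camera adjusted p = 0.204). In all, 1474 of the 5786 tested genes changed, 641 of them higher and 833 lower, 82 and 240 of them by at least 2-fold. Of 36 lists 16 passed camera and 0 did so with an estimated correlation, where camera gave 5 at an unadjusted p under 0.05 and a lowest adjusted p of 0.171.

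Rim101 is activated by cleavage at alkaline pH and represses other repressors, among them NRG1 and SMP1. The labels do not describe the 531 allele. The rim101-531 mutant had the fewest called genes of the 6 mutants. Hypoxic cell wall genes, seripauperins and phosphate genes led what moved. None of these lists was particular to this mutant. At the preset correlation, hypoxic cell wall genes also rose in every other mutant and seripauperins in ste12, dig1 and ras2. The phosphate regulon also rose in ste12, dig1 and spt8. All these comparisons share the wild-type libraries, so a difference of the wild type cannot be told apart from effects of the mutations. TIR2, a cell wall mannoprotein, rose 11.1-fold from 59.0 ± 8.87 to 654 ± 21.3 CPM (log2 fold change 3.47 ± 0.17, adjusted p = 1.16e-10). Hypoxic cell wall genes rose in 5 of 12 cases (7 adjusted over the list alone; camera adjusted p = 1.66e-20). TIR4 had a log2 fold change of 1.25 ± 0.21, TIR3 of 1.11 ± 0.19 and DAN1 of 0.95 ± 0.15. The seripauperins rose in 5 of 5 (5 adjusted over the list alone; camera adjusted p = 8.34e-13). PAU5 had a log2 fold change of 1.10. The phosphate regulon rose in 8 of 16 cases (11 adjusted over the list alone; camera adjusted p = 1.66e-20): PHO89 by 3.69 ± 0.40 on the log2 scale, SPL2 by 2.19 ± 0.43, GIT1 by 1.60 ± 0.19, the acid phosphatase PHO5 by 1.11 ± 0.18 and PHO84 by 1.01 ± 0.13. CSS1 (2.25 ± 0.27) and HES1 (1.49 ± 0.23) rose as well. PAI3, an inhibitor of vacuolar proteinase A, had a log2 fold change of -1.52 ± 0.22, AAD10, an aryl-alcohol dehydrogenase, of -1.35 ± 0.15, UGA4, a permease for gamma-aminobutyrate, of -1.06 ± 0.17, and PGU1 of -0.99 ± 0.15. CIT2, a citrate synthase of the retrograde pathway, rose by 0.84 ± 0.10. Of the Rim101-regulated genes 2 rose and 1 fell of 8 (3 and 1 adjusted over the list alone), ENA1 by 1.05 ± 0.15. The list did not pass camera (adjusted p = 0.120), except without rim101-531 replicate 2 (adjusted p = 0.0459, the lowest over the settings tried, the highest being 0.210). Pathway components of Rim101 fell in 1 of 9 cases (1 adjusted over the list alone; camera adjusted p = 0.266).

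Small shifts of many genes carried other lists in rim101-531. Ergosterol synthesis rose in 6 of 24 cases (14 adjusted over the list alone; camera adjusted p = 6.16e-12, adjusted p = 0.112 with an estimated correlation). Mitochondrial ribosomal proteins fell in 6 of 56 cases (31 adjusted over the list alone; camera adjusted p = 3.40e-16, adjusted p = 0.297 with an estimated correlation). Cytosolic ribosomal proteins lay higher by a median of 0.35 on the log2 scale with none called, over all genes or adjusted over the list alone (camera adjusted p = 2.93e-16, adjusted p = 0.566 with an estimated correlation). The iron regulon fell in 4 of 23 cases (11 adjusted over the list alone; camera adjusted p = 5.56e-07, adjusted p = 0.379 with an estimated correlation). Of the filamentation MAPK target genes 3 of 12 fell (4 adjusted over the list alone, with 1 higher; camera adjusted p = 0.0158, adjusted p = 0.304 with an estimated correlation). That list lost its call without wild-type replicate 2 (adjusted p = 0.0905) and without rim101-531 replicate 2 (adjusted p = 0.177). Cell wall proteins rose in 1 and fell in 1 of 32 cases (1 and 1 adjusted over the list alone; camera adjusted p = 0.889). None of the 8 flocculins and adhesins, the 16 filamentation MAPK pathway components or the 10 galactose pathway genes was called, over all genes or adjusted over the list alone (camera adjusted p = 0.971, 0.674 and 0.232). In all, 178 of the 5786 tested genes changed, 74 of them higher and 104 lower, 23 and 18 of them by at least 2-fold. Of 36 lists 14 passed camera, 3 of them with an estimated correlation. The count was 89 and 94 without wild-type replicates 2 and 3, and 76 and 83 without rim101-531 replicates 2 and 3. It was 61 with only the 6 libraries of both groups in the fit, and 269 with the replicate number as a block. Against the mean of the 5 other mutants it was 331, with 44 of the 178 reported calls kept in direction and 7 called the opposite way. Most calls in rim101-531 thus depended on which reference was used. Of the 62 called genes that the naming rule picked here, 41 lost their call in at least 1 setting, and those named above were not among them.

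Ras2 signals nutrient supply to protein kinase A, which promotes growth and filamentation and holds back the stress response. Most genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation and of the respiratory chain fell in ras2, and the core histones and most cyclins rose. Of these lists only the cyclins passed with an estimated correlation. Genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation fell in 19 of 22 cases (20 adjusted over the list alone; camera adjusted p = 5.78e-18, adjusted p = 0.0715 with an estimated correlation): ADH2, the alcohol dehydrogenase that consumes ethanol, from 9105 ± 71.5 to 2198 ± 102 CPM (log2 fold change -2.05 ± 0.16, adjusted p = 5.35e-08), YAT1 at -1.28 ± 0.10 and YAT2 at -1.31 ± 0.10. Respiratory chain and ATP synthase genes fell in 28 and rose in 1 of 34 cases (31 and 2 adjusted over the list alone; camera adjusted p = 1.52e-15, adjusted p = 0.132 with an estimated correlation), COX13 at -1.07 ± 0.09. The tricarboxylic acid cycle fell in 7 of 17 cases (8 adjusted over the list alone; camera adjusted p = 1.69e-05, adjusted p = 0.375 with an estimated correlation), mitochondrial ribosomal proteins in 23 of 56 (25 adjusted over the list alone; camera adjusted p = 3.46e-06, adjusted p = 0.492 with an estimated correlation). Retrograde targets fell in 5 of 8 (5 adjusted over the list alone; camera adjusted p = 3.04e-05, adjusted p = 0.0715 with an estimated correlation), CIT2 at -0.90 ± 0.10. All 9 tested core histones rose (9 adjusted over the list alone; camera adjusted p = 5.56e-07, adjusted p = 0.138 with an estimated correlation), HTB2 by 1.08 ± 0.13 and HHF1 by 0.91 ± 0.12. Cyclins rose in 7 of 12 cases (8 adjusted over the list alone, with 1 lower; camera adjusted p = 9.91e-05), led by the G1 cyclins CLN2 (1.16 ± 0.13) and PCL1 (0.81 ± 0.12). Heat shock genes fell in 14 of 27 cases (16 adjusted over the list alone; camera adjusted p = 1.39e-06, adjusted p = 0.125 with an estimated correlation), HSP30 from 7568 ± 102 to 2270.2 ± 459 CPM and HSP104, a disaggregase, from 1999 ± 461 to 709 ± 118.

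Single genes moved further in ras2, though for URA3 a selection marker cannot be told apart from regulation. ANS1 went from 0.233 ± 0.403 to 47.1 ± 7.42 CPM, PDC6, a minor pyruvate decarboxylase, rose by 4.22 ± 0.18 on the log2 scale, and HUG1 (2.68 ± 0.29), URA3 (2.65 ± 0.15), PMA2, a plasma membrane proton pump (2.51 ± 0.35), AQY1, a water channel (2.43 ± 0.26), PAU2 (2.42 ± 0.39) and PAU17 (2.32 ± 0.16) followed. The largest falls were of RSB1, a sphingolipid flippase (-3.36 ± 0.21), FDH1, a formate dehydrogenase (-3.34 ± 0.41), SUC2, invertase (-3.22 ± 0.29), URA1 (-2.93 ± 0.25), ZRT1 (-2.68 ± 0.46), CIT3 (-2.61 ± 0.16), PGU1 (-2.53 ± 0.17) and FRE7, a reductase (-2.38 ± 0.39). Filamentation target genes fell in 5 and rose in 1 of 12 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.000161, adjusted p = 0.0905 with an estimated correlation). Pheromone response genes fell in 8 of 22 (8 adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.125 with an estimated correlation), PRM5 at -1.63 ± 0.16. Nitrogen catabolite repression genes fell in 11 and rose in 3 of 23 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00139). Of the ammonium transporters, MEP2 had a log2 fold change of -1.71 ± 0.16 and MEP3 of -1.46 ± 0.19. Hypoxic cell wall genes rose in 9 and fell in 1 of 12 cases (9 and 1 adjusted over the list alone; camera adjusted p = 1.44e-08, adjusted p = 0.0715 with an estimated correlation). Seripauperins rose in 5 of 5 (5 adjusted over the list alone; camera adjusted p = 2.11e-10). The galactose pathway rose in 3 of 10 cases (5 adjusted over the list alone; camera adjusted p = 0.00558, adjusted p = 0.424 with an estimated correlation), where GAL10 stood at 2982 ± 41.7 CPM against 1895 ± 276 and did not pass on its own (adjusted p = 0.0563). The Ras and protein kinase A pathway rose in 5 and fell in 2 of 22 cases (6 and 3 adjusted over the list alone; camera adjusted p = 0.222). CDC25, the exchange factor for Ras, had a log2 fold change of 0.67 ± 0.11. Trehalose and glycogen genes rose in 1 and fell in 2 of 18 (1 and 2 adjusted over the list alone; camera adjusted p = 0.575). Ribosome biogenesis genes rose in 1 of 63 (0 adjusted over the list alone; camera adjusted p = 0.60). In all, 1462 of the 5786 tested genes changed, 598 of them higher and 864 lower, 87 and 129 of them by at least 2-fold. Of 36 lists 18 passed camera, 3 of them with an estimated correlation.

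Rtg3 pairs with Rtg1 to switch on genes that supply glutamate precursors when mitochondria are impaired. The rtg3 mutant asked what this pathway controls in the biofilm. Its known targets fell: 7 of the 8 retrograde genes did so (7 adjusted over the list alone), with a median log2 fold change of -1.33 (camera adjusted p = 1.76e-21). CIT2, the peroxisomal citrate synthase (chromosome III, 120946 to 122328), went from 972 ± 118 to 60.7 ± 5.53 CPM (log2 fold change -4.00 ± 0.12, adjusted p = 4.05e-15), ATO3, an ammonium exporter, had a log2 fold change of -2.98 ± 0.14 and DLD3, a lactate dehydrogenase, of -2.20 ± 0.22. Other large falls were of ADY2, the acetate transporter (-5.76 ± 0.25), CIT3, a mitochondrial citrate and methylcitrate synthase (-4.22 ± 0.18), and PDH1, a dehydratase of the methylcitrate cycle (-4.02 ± 0.14). Genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation fell in 9 and rose in 1 of 22 cases (12 and 2 adjusted over the list alone; camera adjusted p = 1.20e-16, adjusted p = 0.0685 with an estimated correlation). CRC1, a carnitine carrier, had a log2 fold change of -2.73 and ALD4 of -2.41. The tricarboxylic acid cycle fell in 10 of 17 (11 adjusted over the list alone; camera adjusted p = 7.69e-08, adjusted p = 0.294 with an estimated correlation) and the respiratory chain and ATP synthase in 21 of 34, with 1 higher (23 and 1 adjusted over the list alone; camera adjusted p = 2.35e-06, adjusted p = 0.492 with an estimated correlation). Cytosolic ribosomal proteins fell in 34 of 137 cases (48 adjusted over the list alone; camera adjusted p = 3.01e-08, adjusted p = 0.630 with an estimated correlation), RPP0 at -0.87 ± 0.17 and RPL4B at -0.76 ± 0.17.

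Transcripts of cell wall genes also changed in rtg3. TIR2 (chromosome XV, 346195 to 346950) rose 88.1-fold from 59.0 ± 8.87 to 5199 ± 553 CPM (log2 fold change 6.46 ± 0.19, adjusted p = 4.05e-15), while the related TIR1 had a log2 fold change of -4.92 ± 0.30 and CWP1 (chromosome XI, 261132 to 261851) of -5.17 ± 0.24. Cell wall proteins fell in 16 and rose in 3 of 32 cases (17 and 3 adjusted over the list alone; camera adjusted p = 3.76e-12), among them UTR2, a chitin transglycosylase (-3.07), GAS5 (-1.67) and SCW4 (-1.09). Filamentation target genes fell in 7 of 12 cases (8 adjusted over the list alone; camera adjusted p = 1.56e-13): FLO11, PGU1, CHS7, of chitin synthase export (-1.52 ± 0.09), and NFG1 (-1.45 ± 0.18) were the 4 clearest. Flocculins and adhesins fell in 2 of 8 (2 adjusted over the list alone; camera adjusted p = 0.000217, adjusted p = 0.0685 with an estimated correlation), pheromone response genes in 8 of 22 with 0 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0237, adjusted p = 0.166 with an estimated correlation). Hypoxic cell wall genes rose in 7 and fell in 1 of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 1.16e-05, adjusted p = 0.166 with an estimated correlation). The Rim101-regulated genes all moved, 6 up and 2 down of 8, over all genes and adjusted over the list alone (camera adjusted p = 1.49e-08): SMP1, a MADS-box transcription factor, rose by 3.49 ± 0.16, YOR389W by 2.68 ± 0.12 and NRG1, a repressor of filamentation genes, by 2.03 ± 0.15. The further largest rises were of SNO4 (3.11 ± 0.31), HSP33 (2.52 ± 0.21) and HSP31 (2.12 ± 0.11), members of 1 chaperone family with similar copies, ERR3, an enolase-related gene (2.81 ± 0.40), MNC1 (2.46 ± 0.45) and OYE3, an NADPH oxidoreductase (2.24 ± 0.21). The largest fall was of DPI8, from 353 ± 36.6 to 1.65 ± 1.21 CPM (log2 fold change -7.77 ± 0.22). The galactose pathway rose in 2 and fell in 1 of 10 cases (5 and 1 adjusted over the list alone; camera adjusted p = 0.137). In all, 1185 of the 5786 tested genes changed, 539 of them higher and 646 lower, 71 and 152 of them by at least 2-fold. Of 36 lists 19 passed camera, 4 of them with an estimated correlation. The count was 735 without rtg3 replicate 1, 719 without rtg3 replicate 3, and 2040 against the mean of the 5 other mutants.

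**Figure D3:**
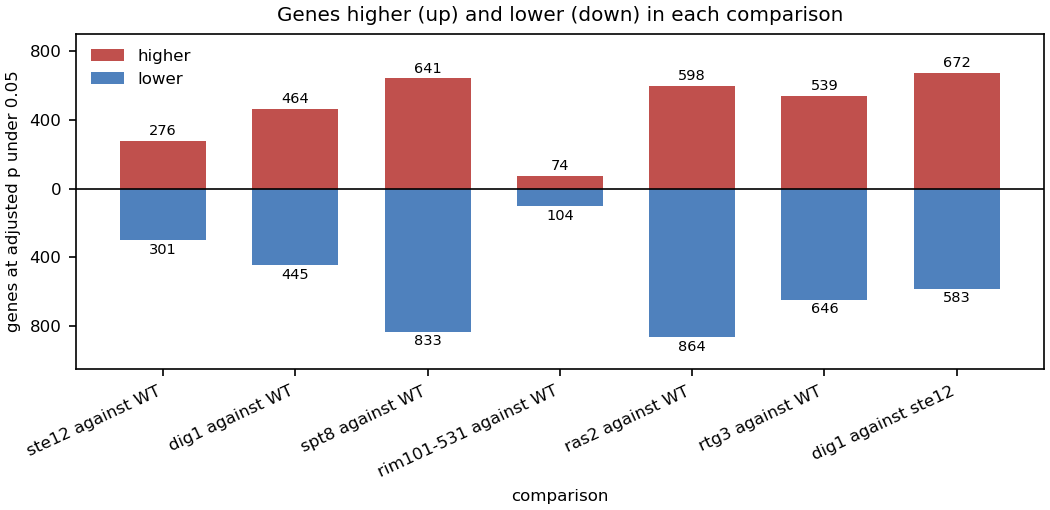
Number of genes called at adjusted p under 0.05 in each comparison, drawn as bars above 0 for genes higher in the strain named at the start of the comparison and below 0 for genes lower. The shortest bars are those of rim101-531 (74 higher and 104 lower), and the longest are 672 higher in dig1 against ste12 and 864 lower in ras2.

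**Figure D4:**
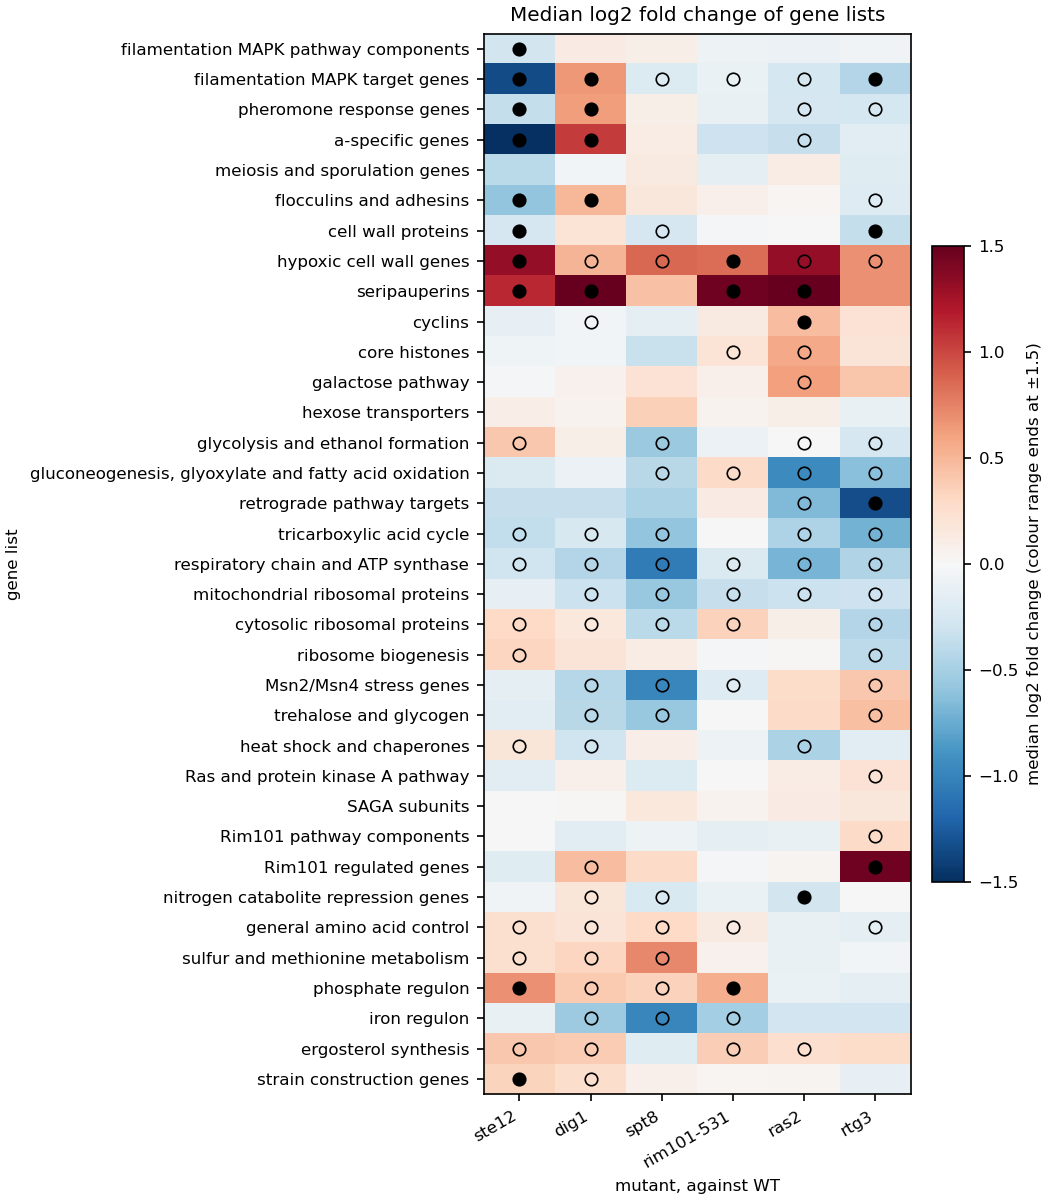
Median log2 fold change of the members of gene lists in each mutant against the wild type (colour, with the scale ending at 1.5 on either side of 0), where an open circle marks a list that passed camera and a filled circle one that also passed with an estimated correlation. The filamentation target genes have medians of -1.34 in ste12 and 0.65 in dig1, and the retrograde targets -1.33 in rtg3.

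The 5 hypofilamentous mutants share a phenotype in the labels, so the genes changed the same way in all 5 were counted. There were 20, 14 higher and 6 lower than in the wild type. PGU1 fell in all 5 (log2 fold changes from -3.79 to -0.99), as did RIB4 (-2.10 to -0.69), while HES1 (1.49 to 2.30), TIR2 (1.40 to 6.46) and PDR11, a sterol transporter (0.62 to 0.94), rose in all 5. FLO11 was not among them, since it did not pass in rim101-531. In dig1 14 of the 20 changed in the direction of the hypofilamentous mutants, 5 did not pass, and 1, PGU1, changed the other way. With dig1 in place of the wild type as reference, 225 genes differed the same way in all 5, 18 higher and 207 lower. Unchanged groups simulated against the same wild-type libraries gave at most 0 such genes by edgeR in 20 simulations (13 at an unadjusted p under 0.05), and independent lists of these sizes would share 0.00377 higher and 0.0130 lower genes. The simulated value leaves out the effects and the expected one the shared libraries, so neither measures a shared effect. Of the 16 of these genes that the naming rule picks, 11 lost a call in at least 1 mutant and setting and 5, those named here, did not. The count was 8 without wild-type replicate 2 and 10 with the 2 groups of each comparison alone in the fit. It was 31 with the replicate number as a block.

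Across 5040 genes the log2 fold changes of pairs of mutants correlated between -0.02 (dig1 and rtg3) and 0.50 (spt8 and rim101-531), over 15 pairs. Genes are not independent replicates, and unchanged groups simulated against the same wild-type libraries gave 0.504 and 0.504 for these pairs. The covariance was -0.00437 for dig1 and rtg3 (simulated 0.0174), 0.0267 for ste12 and dig1 (simulated 0.0174), 0.0711 for spt8 and rim101-531 (simulated 0.0177) and 0.0814, the highest, for dig1 and spt8 (simulated 0.0175). Among called genes, ste12 and dig1 shared 80 higher and 44 lower genes, where independent lists would share 22.1 and 23.1, and 119 genes went opposite ways. Loss of SPT8 and of RAS2 lowered 334 genes in common (expected 124) and raised 161 (expected 66.2), with 129 in opposite directions. The 3 wild-type libraries could not be divided into groups of at least 2, so part of any excess may come from the shared controls.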

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

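The tests of the ste12 share and of the ribosomal protein genes were chosen only after the results were seen. The shares of alignment records that no comparison used lay above the wild type in 5 cases. Records aligned to more than 1 place made up 27.9% ± 0.654 of all records in dig1 and 24.3% ± 0.759 in spt8, against 21.2% ± 0.417 in the wild type (n = 3 libraries each). Records on no feature made up 20.6% ± 0.278 in ras2 against 19.9% ± 0.0868. Ambiguous records made up 1.74% ± 0.0822 in ste12 and 1.65% ± 0.0182 in ras2 against 1.43% ± 0.0724. In each of these 5 cases all 3 libraries of the mutant lay above all 3 of the wild type. In other cases all 3 lay below: records aligned to more than 1 place in ras2 (18.8% ± 0.264) and rtg3 (18.8% ± 0.205), records on no feature in dig1 (17.8% to 18.2%) and spt8 (18.2% ± 0.164), and ambiguous records in spt8 (1.28% ± 0.0514). An exact permutation test of 3 libraries against 3 cannot go below 0.1, and groups of 3 were not examined for outlying libraries.

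The share of multiply aligned records in dig1 stood furthest from the wild type. A candidate explanation is transcripts of Ty1 retrotransposons, which carry Ste12 binding sites and share sequence among their copies: the 4 tested of 61 annotated Ty1 frames had a median log2 fold change of 0.52 in dig1, 1 of them called, with a summed level of 30.5 ± 5.30 CPM against 17.5 ± 2.35, which met the criterion set beforehand. In ste12 the same sum was 7.76 ± 0.773 CPM with 3 of the 4 frames lower and 1 higher, yet the share of multiply aligned records was 20.8%, close to the wild type. So few frames have unique reads that this leaves the explanation open. Duplicated ribosomal protein genes stay open too: their median log2 fold change was 0.16 in dig1, in counts that leave out the multiply aligned records.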

How the results depend on the processing

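The comparison with the mean of the other mutants was chosen only after the results were seen, and every other alternative before the data were examined. Counts of called genes or lists stayed within 1.5 times the reported ones in 8 of 8 cases with DESeq2, 14 of 14 with DESeq2's size factors, 8 of 8 without the filter, 87 of 96 with a library left out and 4 of 8 with only the libraries of both groups in the fit. Without 1 library, the count of changed genes ran from 357 to 456 in ste12 (reported 577; lowest without wild-type replicate 3), 76 to 176 in rim101-531 (reported 178; lowest without rim101-531 replicate 2), 719 to 1068 in rtg3 (reported 1185; lowest without rtg3 replicate 3), and 8 to 27 for the genes shared by the 5 hypofilamentous mutants (reported 20; lowest without wild-type replicate 2). With only the libraries of both groups in the fit it was 385 in dig1, 61 in rim101-531, 603 between dig1 and ste12 and 10 for the shared genes. In that fit, which estimates the spread from fewer libraries, it was also lower in ste12 (409) and spt8 (1121). It was higher than reported in ras2 (1565) and rtg3 (1602). Against the mean of the 5 other mutants it was 1581 in ste12, 331 in rim101-531 and 2040 in rtg3. The reference there differs in both its strains and its number of libraries. Of the reported calls of these 3 mutants, 73.0%, 24.7% and 72.6% were kept in direction. With an estimated correlation, camera passed 11 lists in ste12, 5 in dig1, 0 in spt8 (5 at an unadjusted p under 0.05), 3 in rim101-531, 3 in ras2 and 4 in rtg3. Among lists called in the reported or the alternative fit, the direction of 3 turned, each without 1 library. Without dig1 replicate 2, cytosolic ribosomal proteins turned in dig1 (camera adjusted p = 0.0553, range over the left-out libraries 2.32e-09 to 0.0770). Ribosome biogenesis turned there too (adjusted p = 0.0140, range 0.000221 to 0.758). It also turned in rim101-531 without rim101-531 replicate 2 (adjusted p = 0.0256, range 0.0256 to 0.951). The cause was not tested. Of the 1296 list results with a library left out, 1210 kept their side of the threshold, 39 lost their call and 44 gained one. Those called in both fits kept their direction, and the direction of lists called in neither was not compared. Of the 4674 such results for genes picked by the naming rule, 4208 kept theirs, 440 lost a call and 26 gained one, and with DESeq2 750 of 779 kept theirs. At this depth, genes with low counts could pass only with large changes.

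The labels number the replicates 1 to 3 in every group without saying that a number marks a shared culture or day. Over 5040 genes, deviations from the group means of libraries with the same number correlated with a median r of 0.48 for number 1 (range -0.46 to 0.77 over 21 pairs of groups), 0.50 for number 2 (-0.49 to 0.78) and 0.01 for number 3 (-0.09 to 0.11). Among the libraries of ste12, dig1, spt8, rim101-531 and ras2, wild-type libraries 1 and 2 correlated best with the one of their own number. Libraries 1 and 2 of rtg3 ran the opposite way. Wild-type library 3 correlated best with its own number in no mutant. In every group libraries 1 and 2 differed most, in the wild type with a chi-square per degree of freedom of 19.8 against 3.99 and 8.23. Number 3 thus lay between them, where deviations from a group mean are small, so its low r does not exclude pairing. Part of the libraries share deviations, which stay in the spread of the reported fit. Whether the numbers pair all samples is left open. The simulated groups hold no such shared deviations. With the replicate number as a block, the count of changed genes was 774 in ste12, 1107 in dig1, 1789 in spt8, 269 in rim101-531, 1771 in ras2, 1618 in rtg3, 1442 between dig1 and ste12 and 31 for the shared genes, of which that of rim101-531 and that of the shared genes moved by more than 1.5 times; the cause was not tested.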

Other observations

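The lists of this part and all its tests were chosen only after the results were seen, apart from the lists of strain construction and Rim101-regulated genes, the simulated count, the count without 1 wild-type library and the splits of the libraries. Lists of zinc, pyrimidine and DNA damage genes were drawn up around genes already seen among the largest changes, and contain them, so their members are only counted here. Zinc genes that rose in dig1 included ZPS1 (log2 fold change 4.75 ± 0.46), the transporter ZRT1 (3.16 ± 0.45), the zinc-regulated alcohol dehydrogenase ADH4 (1.92 ± 0.22) and ZAP1 (1.26 ± 0.26), which encodes the zinc-responsive activator. ZRT1 went the other way in spt8 (-1.78 ± 0.44), ras2 (-2.68 ± 0.46) and rtg3 (-2.86 ± 0.46). Of 16 genes under Zap1, 9 rose and 0 fell in dig1, 4 and 1 in ste12, 5 and 5 in spt8, 2 and 0 in rim101-531, 2 and 3 in ras2, and 2 and 3 in rtg3.

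Of 6 genes of pyrimidine synthesis other than URA3, 3 fell in ste12, 3 in dig1, 4 in spt8, 1 in rim101-531, 4 in ras2 and 4 in rtg3, and none rose. The medians on the log2 scale were -0.55, -0.80, -0.91, -0.57, -1.04 and -0.75. URA3, whose product acts last in this route and which is also a selection marker in strain construction, rose in ste12 (2.36 ± 0.16) and ras2 (2.65 ± 0.15). Other genes used in strain construction also differed: HIS3 rose in dig1 (1.24 ± 0.18) and spt8 (0.60 ± 0.19) and fell in ste12 (-0.78 ± 0.22) and rtg3 (-0.76 ± 0.20), LEU2 rose in spt8 (0.99 ± 0.11) and fell in rtg3 (-0.44 ± 0.11), and MET17 rose in dig1 (1.28 ± 0.31) and spt8 (1.57 ± 0.31). ADE2 rose in ste12 (0.56 ± 0.16), HO, the mating type endonuclease, in ras2 (1.66 ± 0.21) and rtg3 (0.64 ± 0.21), and TRP1 (-0.56 ± 0.13), CAN1 (-0.35 ± 0.09) and LYP1 (-0.41 ± 0.12) fell in ras2. Of 12 DNA damage response genes, 6 rose and 2 fell in ras2, 4 and 1 in ste12, 4 and 1 in dig1, 5 and 1 in spt8, 3 and 0 in rim101-531, and 4 and 0 in rtg3.

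Although dig1 and the other mutants have opposite phenotypes, 14 genes changed the same way in all 6, among them PAU5, HES1, PDR11 and RIB4. In the 5 hypofilamentous mutants HES1, PDR11 and RIB4 kept their calls in every setting, and PAU5 did not. Unchanged groups simulated against the same wild-type libraries gave at most 0 genes shared by all 6 by edgeR (10 at an unadjusted p under 0.05). Such groups give almost no calls in any comparison, so this does not settle whether the shared libraries are the source. A single outlying wild-type library could be the source: the count was 22, 5 and 11 without wild-type replicates 1, 2 and 3, and the lowest, 5, met the criterion set beforehand for this explanation. A later test took the genes called without a library and measured that library against the mutants, where the left-out libraries lay a median of 0.88, 1.37 and 1.18 from the mutants' mean on the log2 scale, 0.775, 1.04 and 0.898 of the distance of the libraries used, which argues against 1 library as the whole cause. The wild type differed from the mean of the 6 mutants in 674 genes (475 higher and 199 lower), and a difference of the wild-type strain or its handling cannot be told apart from the mutations, since the labels give 1 wild-type strain.

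Genes regulated by Rim101 differed between rtg3 and rim101-531. Set against each other, 6 of 8 were higher in rtg3 and 2 lower (adjusted p for single genes from 1.82e-12 to 0.000136). NRG1 differed by 2.07, SMP1 by 2.50, ENA1 by -3.10 and CWP1 by -4.83 on the log2 scale. Against the wild type, RIM8 (0.89 and -0.74) and ENA1 (-2.05 and 1.05) went opposite ways in rtg3 and rim101-531. SMP1 rose in both (3.49 and 1.00), and NRG1 only in rtg3 (2.03 and -0.05). The labels do not describe the 531 allele, so rim101-531 cannot be taken here as a loss of Rim101 function. The rim101-531 calls of RIM8 and SMP1 did not hold in every setting (highest adjusted p = 0.0763 and 0.0724). Exchanged labels are argued against by RTG3, which had no count in the libraries labelled rtg3 and at least 109 in each labelled rim101-531, although the names of the deposited files give both groups the same strain number and counts leave the rim101-531 label itself unchecked. A lower RIM101 transcript is argued against by its log2 fold change of 0.26 in rtg3. A second lesion in the Rim101 pathway of the rtg3 strain cannot be told apart from an effect of Rtg3, since all pathway genes had counts there, the smallest total being 136, and a lesion that leaves the transcript is not seen in counts. A link from Rtg3 to Rim101-regulated genes may exist as a hypothesis, which these libraries cannot separate from that.

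The libraries of each comparison were also split in every other way into groups of 3. The 10 splits of 6 libraries are too few for a share under 0.05. Every split but the real one also mixes libraries of both strains within a group, which widens the spread. Low counts there do not settle whether chance labels give as many genes. The real split gave 577 genes in ste12 (highest other 1), 909 in dig1 (0), 1474 in spt8 (0), 178 in rim101-531 (0), 1462 in ras2 (0), 1185 in rtg3 (0) and 1255 between dig1 and ste12 (339), so 1 split of each gave as many, the real one. The other split of dig1 and ste12 with 339 genes set dig1 replicates 1 and 3 and ste12 replicate 1 against the rest. This parts the libraries numbered 1 from those numbered 2. So does the split of dig1 replicate 1 and ste12 replicates 1 and 3 against the rest, which gave 0 genes. For the genes changed the same way in all 5 hypofilamentous mutants, 2 of 100 relabellings of the 18 libraries, the real one included, gave at least 20 genes. The other one took the 3 rtg3 libraries as the reference and gave 103 genes, several times the real count, which points to a structure of the samples: the reference was 1 strain only in these 2. The remaining 98, with mixed references, gave none, so they do not settle whether chance labels give such a count.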
